A study of Mus musculus with 12 samples.

How the data were processed

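RNA from dendritic cells of C57BL/6 mice was measured on 12 Affymetrix Mouse Exon 1.0 ST arrays in a design of 2 tissues by 2 genotypes, with 3 arrays in each of the 4 groups. Per the labels, splenic CD11c+ cells were obtained by magnetic sorting, and CD11c+CD103+ cells of the mesenteric lymph nodes (MLN) were flow-sorted from pools of 4 mice. The Cre+ mice lacked the TGF-beta receptor gene Tgfbr2 in dendritic cells, and Cre- mice were the controls. Groups were taken from sample titles and genotypes. A cell type field of the MLN Cre+ samples named Cre- mice, against their title, source and genotype fields, and the latter were followed. For spleen, the number of mice behind each sample was not given in the sources used here. P-values there rest on the spread between arrays within groups, pooled over both tissues.

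The deposited values were gene-level log2 expression values made by robust multi-array averaging (RMA) in GeneSpring, per the labels, and that they are on the log2 scale was read from their range. The software version and the probe annotation used by the authors were not given in the sources used here. The table held 23332 probe sets and 12 columns, each matched to a sample by its name. Array medians lay between 7.03 and 7.08 in spleen and between 6.74 and 6.89 in MLN. The SD over probe sets was 2.37 to 2.42 in spleen and 1.80 to 1.91 in MLN. Among the 100 lowest values of each array, arrays of the same tissue shared a median of 7 exact values (range 0 to 11 over 30 pairs), whereas none of the 36 pairs of arrays from different tissues shared any. These values show that the tissues carry different value distributions, as separate normalization runs would give, so levels set across tissues depend on the scaling. The number of arrays limits the precision. RMA values carry no detection call, so none was used.

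Probe sets were named through the platform annotation. Of these, 14996 had 1 gene symbol (14860 genes), 1019 had several and were not named, and 7317 had none and stay unnamed here. For 14941 of the 1-symbol probe sets the gene identifier was found in a gene table of the mouse assembly GRCm38.p6, and no symbol needed an update. That table also gave the X and Y assignments. Probe sets with several symbols or none had no chromosome assignment. The build behind the deposited values was not given in the sources used here, so no coordinates are printed.

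The values were analysed as deposited in limma 3.58.1 (R 4.3.3). A linear model with 4 group means was fitted to all 12 arrays, so that the groups shared the estimate of the spread for each probe set, with 8 residual degrees of freedom and 2.66 prior degrees of freedom from eBayes. The contrasts were Cre+ minus Cre- in spleen, Cre+ minus Cre- in MLN, the MLN difference minus the spleen difference, the mean of both differences, and MLN Cre- minus spleen Cre-. Tests were two-sided with Benjamini-Hochberg adjustment over all 23332 probe sets within a contrast, and a probe set was called at an adjusted p under 0.05. Every adjusted p of a gene is from this limma fit. Tgfbr2 and the Y-linked genes were also compared with an exact permutation test, which cannot give a two-sided p under 0.1 with 3 arrays against 3.

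Before the data were examined, 28 gene lists were fixed (pathways, dendritic cell subsets, other cell types a sort could hold, stress and ribosomal genes, and sex-linked genes), together with the tests, the alternatives and the rule for naming genes. Each gene entered a list through its probe set of highest mean. The 27 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a contrast. Each was tested again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. The naming rule took Tgfbr2, up to 12 largest rises and 12 largest falls among called probe sets with 1 symbol, leaving out predicted genes and, for the comparisons of 2 groups, genes whose arrays overlapped. It also took the 4 members of each list with the smallest p and the 3 members of highest mean of each other-cell-type list. Genes outside the rule are marked where they occur.

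The steps were tested on simulated data with the spread of these arrays. Noise was drawn independently for each probe set and array, without correlation between genes. The shares recovered and falsely called there need not hold for the real arrays. Of 100 probe sets changed by 2-fold, 78% were recovered in the simulated spleen comparison and 75% in the simulated MLN comparison of 23332 probe sets. Of 100 changed by 1.5-fold, 38% and 39% were recovered, and 4 of the 120 and 4 of the 118 calls were false. Alternatives were quantile normalization over all arrays, a shift of every array to 1 median, a filter on dim probe sets (highest group mean above the 40th percentile, 6.37, which kept 15737), probe sets with 1 symbol alone, a trended and robust variance, array weights, replicate blocks, other thresholds, the arrays of 1 tissue alone, and each array left out in turn. Leaving out probe sets on X and Y was chosen after seeing the data.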

Results

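Gene expression was compared between Cre+ mice, in which dendritic cells (DC) lacked the TGF-beta receptor gene Tgfbr2, and Cre- controls, in splenic CD11c+ DC and in CD11c+CD103+ DC of the MLN. Each of the 4 groups had 3 arrays. CD103+ DC are the migratory DC that carry antigen from the gut wall to the MLN. The deposited log2 values of 23332 probe sets were used without further scaling. Arrays of a group correlated with r of at least 0.984 in spleen and 0.982 in MLN, across probe sets, which are not independent replicates.

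The deleted gene was examined first. Tgfbr2 measured 10.94 ± 0.02 (SD, n = 3) in spleen Cre- and 10.70 ± 0.03 (SD, n = 3) in spleen Cre+, a level of 84.7% of control with a 95% interval of 75.5 to 95. In MLN it measured 9.58 ± 0.08 and 9.46 ± 0.08 (SD, n = 3 each), 92.1% of control with an interval of 82.1 to 103. The log2 differences were -0.24 (SE 0.075, adjusted p = 0.138) and -0.12 (SE 0.075, adjusted p = 0.524), so neither passed the threshold in limma. The 3 Cre+ arrays lay below the 3 Cre- arrays in both tissues, for which the exact permutation p was 0.1, the smallest it can give. Which exons were deleted was not given in the sources used here. A gene-level value covers probes outside the deleted part, so these values do not measure the deletion.

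Y-linked genes separated the splenic groups. Eif2s3y measured 9.91 ± 0.14 in spleen Cre- and 3.17 ± 0.14 in spleen Cre+ (SD, n = 3 each), and Kdm5d 8.23 ± 0.19 and 4.31 ± 0.16. The log2 differences were -6.73 (adjusted p = 1e-04) and -3.92 (adjusted p = 0.000625), so both genes fell. Every Cre- spleen array thus carried male-typical and every Cre+ spleen array low values of both genes, and genotype and sex cannot be told apart in spleen. In the MLN pools Eif2s3y measured 7.42 ± 1.0 in Cre- and 7.60 ± 0.59 in Cre+ (SD, n = 3 each), a difference of 0.18 (SE 0.421, adjusted p = 0.885), and that of Kdm5d was -0.04 (SE 0.327, adjusted p = 0.97).

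**Figure D1:**
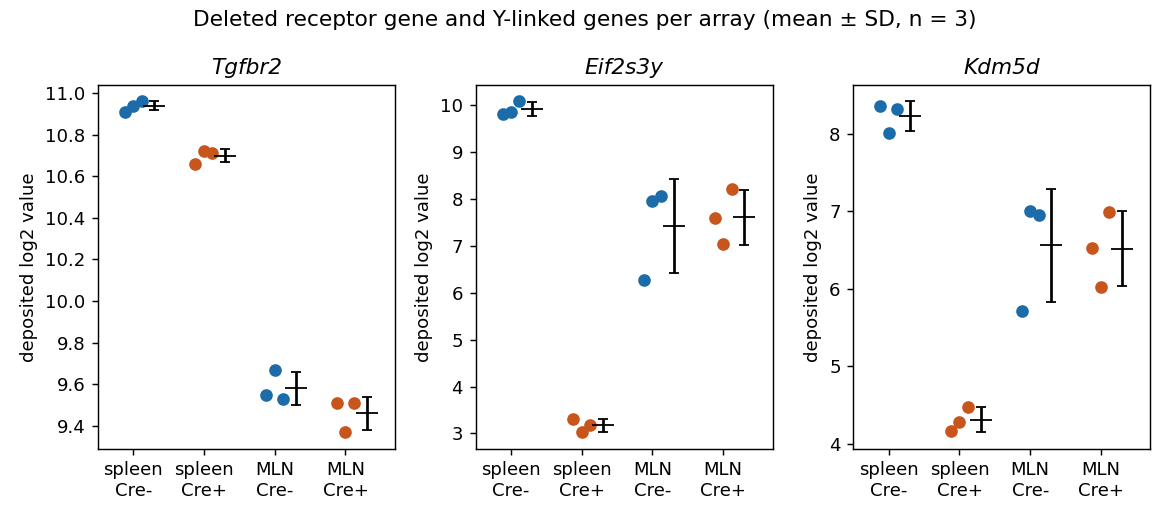
Deposited log2 values of Tgfbr2, Eif2s3y and Kdm5d per array (blue points Cre-, orange points Cre+), with the mean and SD of 3 arrays beside each group and a separate vertical scale for each gene. Eif2s3y lay between 9.81 and 10.07 in spleen Cre- and between 3.03 and 3.31 in spleen Cre+, while the MLN groups overlapped.

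In splenic DC, 10 of 18 neutrophil genes, 10 of 24 type I interferon-induced genes and 9 of 25 proliferation genes rose in Cre+ against Cre- mice, and 6 of 23 macrophage genes fell. Camera called each of these lists, and each call was lost at adjusted p = 0.183 with an estimated correlation. The largest rise was that of Chil3, a chitinase-like protein of myeloid cells, by 2.85 (SE 0.284) from 5.06 to 7.92 on the log2 scale. The granule proteins Ngp and Ltf rose by 2.70 (SE 0.215) and 2.29 (SE 0.248), the siderophore-binding Lcn2 by 2.27 (SE 0.234), the antimicrobial peptide gene Camp by 1.96 (SE 0.278) and the calcium-binding S100a9 by 1.66 (SE 0.34). Also higher were Gzmk, a granzyme of lymphocytes (2.13, SE 0.438), the phospholipase Plcb4 (2.06, SE 0.176), Spon1 (1.75, SE 0.263), Ly6i (1.75, SE 0.307), the interferon-induced GTPase Tgtp1 (1.67, SE 0.309) and Taar7b (1.64, SE 0.335). Beside the Y-linked genes, the largest falls were those of the collagen gene Col14a1 by 1.73 (SE 0.279), Pcolce2 by 1.47 (SE 0.173), the C-type lectin gene Cd209c by 1.35 (SE 0.133), Speer4f1 by 1.31 (SE 0.216), the cationic amino acid transporter Slc7a2 by 1.31 (SE 0.176), the haemoglobin scavenger receptor Cd163 by 1.28 (SE 0.119), Galnt3 by 1.22 (SE 0.122), Dmpk by 1.18 (SE 0.134), Clec4b2 by 1.14 (SE 0.258) and the integrin gene Itga9 by 1.10 (SE 0.148). Adjusted p for these genes ranged from 0.000467 for Ngp to 0.0496 for Clec4b2. In all, 507 probe sets passed the threshold, of which 290 rose and 217 fell, and 3779 had an unadjusted p under 0.05 against 1167 by chance. Leaving out probe sets assigned to X and Y, 486 of these calls stood. Only 313 of the 507 had 1 symbol, and the others had no chromosome assignment and stayed in. Sex effects on other chromosomes are not removed by that either.

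Gene lists described these changes in spleen. Of the 18 neutrophil genes, 10 rose and 8 did not pass the threshold (14 rose adjusted over the list alone), with a median of 1.02. Csf3r, the receptor for granulocyte colony-stimulating factor, had -0.04 (adjusted p = 0.956). Of the 24 type I interferon-induced genes, 10 rose, among them the antiviral genes Oas2 by 1.55, Oasl2 from 8.63 to 10.13, Rtp4 by 1.05 and Ifit2 by 0.87, and Bst2, which is also a plasmacytoid DC marker, fell by 0.65 (20 rose and 1 fell adjusted over the list alone). Of the 16 interferon-gamma-induced genes, 5 rose (9 adjusted over the list alone), including the guanylate-binding protein Gbp2 by 1.54, the chemokine Cxcl9 by 1.38 and Irgm1 by 1.12. All 25 proliferation genes had positive differences, and 9 rose (22 adjusted over the list alone), with the kinesin Kif11 at 0.86, the kinase Bub1 at 0.82 and the proliferation antigen Mki67 at 0.80. Of the 15 monocyte genes 6 rose (8 adjusted over the list alone), including Fcgr4 by 1.25 and Clec4e by 1.01. Among 16 antigen presentation genes 3 rose (4 adjusted over the list alone), namely the peptide transporter Tap1 by 0.57, H2-Oa by 0.47 and H2-DMa by 0.36. Of the 21 cDC1 genes, Ifi205 rose by 0.90 and 20 did not pass (3 rose adjusted over the list alone).

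Of 23 macrophage genes 6 fell in spleen and 17 did not pass the threshold (11 fell adjusted over the list alone), and of 16 plasmacytoid DC genes 4 fell and 12 did not pass (6 fell and 2 rose adjusted over the list alone). Both lists were called as lower by camera and lost at adjusted p = 0.183 with an estimated correlation. The macrophage genes that fell included the prostaglandin-degrading Hpgd by 0.80, the receptors of dying cells Mertk by 0.79 and Axl by 0.78, and the lectin Fcna by 0.89. The plasmacytoid DC genes that fell were those of the chemokine receptor Ccr9 by 0.82, Cd300c by 0.79, Bst2 by 0.65 and Upb1 by 0.46. Camera called these 9 lists in spleen, with adjusted p from 2.75e-19 for proliferation and 1.73e-15 for type I interferon to 0.00138 for antigen presentation. None held with an estimated correlation. For 7 of the lists the adjusted p = 0.183 with an estimated correlation, for antigen presentation adjusted p = 0.541 with an estimated correlation and for cDC1 adjusted p = 0.759 with an estimated correlation. The Y-linked difference moved with every one of these lists. The antigen presentation list was also lost without spleen Cre+ replicate 1 (adjusted p = 0.0504), and fry did not call the cDC1 list (adjusted p = 0.202). Where the median, mean and test of a list differed in sign, in this or another comparison, the list was not called.

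No member of the TGF-beta pathway list passed the threshold in spleen: of 30 genes, 0 were called over all genes and 0 adjusted over the list alone (limma), and the receptor gene Tgfbr1 had the smallest p, at -0.44 (SE 0.111, adjusted p = 0.0762). That list was called only after quantile normalization (mean -0.07, adjusted p = 0.0385). Among 27 cytokine genes Tnf rose by 0.79 and Il1a fell by 0.70, with the same count adjusted over the list alone, and among 36 chemokine and chemokine receptor genes 3 rose and 2 fell (8 rose and 3 fell adjusted over the list alone), including Cxcl11, which rose by 0.99, and Ccl24, which fell by 0.64. The camera tests of both lists gave adjusted p = 0.0544 and adjusted p = 0.0509, whereas fry called both (adjusted p = 0.0145 and adjusted p = 0.00764), as did camera the chemokine list with all probe sets of a gene (adjusted p = 0.0493). No member was called in the costimulation, retinoic acid, Notch, stress, core conventional DC, T cell, plasma cell, NK, erythroid, mast cell, stroma or ribosomal lists. Clec4a4 rose and Mgl2 fell among the 24 cDC2 genes (2 rose and 1 fell adjusted over the list alone), Cd22 rose among the 17 B cell genes (2 rose and 2 fell adjusted over the list alone), and Clec1b and Rab27b fell among the 14 megakaryocyte genes (1 rose and 2 fell adjusted over the list alone). Camera's adjusted p for the 18 lists not called ran from 0.0509 to 0.975.

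Single arrays held some of these lists back in spleen. T cell and NK genes were called as higher without spleen Cre+ replicate 1 (adjusted p = 1.19e-08 and adjusted p = 0.00511), erythroid genes without spleen Cre+ replicate 2 (adjusted p = 0.00308) and B cell genes without spleen Cre- replicate 3 (adjusted p = 0.00634). Costimulation and stress genes were called without spleen Cre+ replicate 3 (adjusted p = 0.00262 and adjusted p = 0.00549). Plasma cell genes were called without spleen Cre- replicate 3 (adjusted p = 0.0416) or spleen Cre+ replicate 2 (adjusted p = 0.0474). Cytokine genes were called without spleen Cre- replicate 2 (adjusted p = 0.0353), spleen Cre+ replicate 3 (adjusted p = 0.0159) or MLN Cre+ replicate 1 (adjusted p = 0.0449). Chemokine genes were called without spleen Cre- replicate 3 (adjusted p = 0.0118), spleen Cre+ replicates 2 (adjusted p = 0.0297) and 3 (adjusted p = 0.0273), or MLN Cre+ replicates 1 (adjusted p = 0.0449) and 2 (adjusted p = 0.0425).

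The spleen count depended on the arrays in the fit. It was 196 without spleen Cre- replicate 1, 211 without Cre- replicate 2 (99 rose and 112 fell), 265 without Cre+ replicate 1, 141 without Cre+ replicate 2, 300 without MLN Cre- replicate 2 and 305 without MLN Cre+ replicate 2. It was 286 after quantile normalization and 18 when the 6 splenic arrays were fitted alone. Of the 61 named genes called in spleen, 25 stayed called in each of the 12 omissions, among them Chil3, Ngp, Lcn2, Cd163, Cxcl9, Kif11 and Mki67, and 61 kept their direction.

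**Figure D2:**
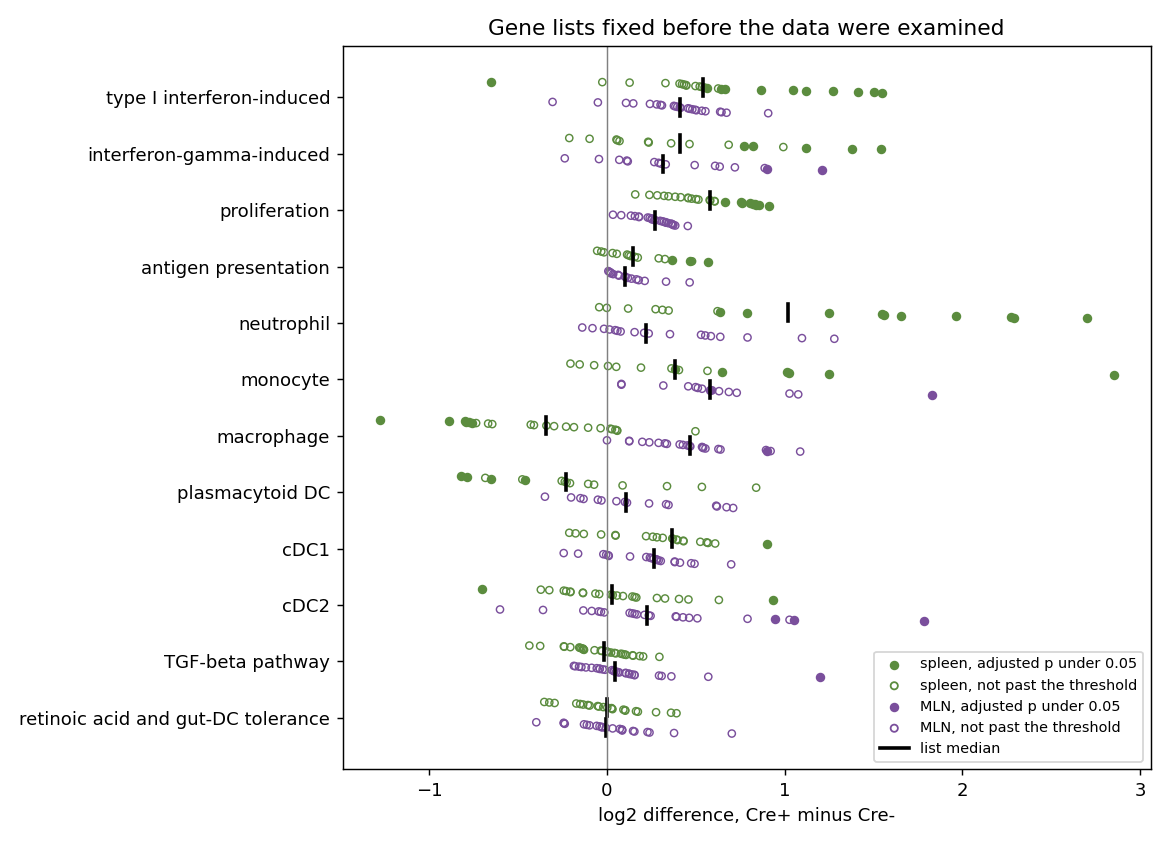
Log2 differences, Cre+ minus Cre-, of the members of 12 gene lists in spleen (green) and MLN (purple), with filled points past the threshold and black bars at the list medians. The macrophage medians were -0.34 in spleen and 0.46 in MLN, and the neutrophil medians 1.02 and 0.22.

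In CD103+ DC of the MLN, 2 of 15 monocyte, 1 of 23 macrophage and 3 of 24 cDC2 genes rose in Cre+ against Cre- mice. Camera called these lists as higher, and the calls were lost at adjusted p = 0.217, adjusted p = 0.393 and adjusted p = 0.397 with an estimated correlation. The Fc receptor gene Fcgr4 rose by 1.83 (SE 0.232, adjusted p = 0.0253), the C-type lectin genes Clec4a3 by 1.78 (SE 0.21, adjusted p = 0.0186) and Clec4a1 by 1.05 (SE 0.127, adjusted p = 0.0186), and Itgam, which encodes CD11b, by 0.95 (SE 0.112, adjusted p = 0.0186). Adgre1, which encodes the macrophage marker F4/80, rose by 0.90 (SE 0.129, adjusted p = 0.0332), and Tgfbi, named for its induction by TGF-beta, by 1.20 (SE 0.164, adjusted p = 0.0321). Further rises were those of Cd300ld by 1.22, the interferon-gamma-induced chemokine Cxcl9 by 1.21, the xanthine dehydrogenase gene Xdh by 0.97, the GTPase gene Gbp7 by 0.90, Fcgr3 by 0.58 and Tm6sf1 by 0.53. The tight junction gene Cldn1 fell by 1.34 (SE 0.151, adjusted p = 0.0186), the phosphatase inhibitor gene Ppp1r1a by 0.98 (SE 0.117, adjusted p = 0.0186) and the transporter gene Slc6a13 by 0.46 (SE 0.0657, adjusted p = 0.0332). In all 20 probe sets passed the threshold, of which 17 rose and 3 fell, and 2783 had an unadjusted p under 0.05 against 1167 by chance.

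Most members of the called lists did not pass the threshold singly in MLN. All 23 macrophage genes had positive differences with a median of 0.46, and 1 rose (14 adjusted over the list alone); the iron transporter Slc11a1 had 0.92 (adjusted p = 0.0856) and Cd5l 1.09 (adjusted p = 0.0856). All 15 monocyte genes had positive differences with a median of 0.58, and 2 rose (11 adjusted over the list alone). Of 24 cDC2 genes 3 rose (8 adjusted over the list alone), and of 16 interferon-gamma-induced genes 2 rose (8 adjusted over the list alone). No type I interferon-induced gene was called over all genes and 15 of 24 rose adjusted over the list alone, with Oasl2 at 0.91 (adjusted p = 0.214) and Irf7 at 0.67 (adjusted p = 0.216). All 25 proliferation genes were positive and 0 were called by either adjustment. All 16 NK and cytotoxic genes were positive, and 0 were called (8 adjusted over the list alone), with the transcription factor Tbx21 at 0.74 (adjusted p = 0.0856). The median MLN difference of all probe sets was itself 0.08 as deposited. After quantile normalization 21 of 23 macrophage, 14 of 15 monocyte, 23 of 25 proliferation and 12 of 16 NK genes were positive. For plasma cell genes 0 of 13 were called (5 adjusted over the list alone), for cDC1 genes 0 of 21 (4 adjusted over the list alone) and for neutrophil genes 0 of 18 (4 adjusted over the list alone).

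Camera called 11 lists in MLN. Macrophage (adjusted p = 2.47e-10), monocyte (2.47e-10), type I interferon (2.46e-08), interferon-gamma (4.12e-06), proliferation (1.19e-05), NK (0.000118), cDC2 (0.000656), plasma cell (0.00146), cDC1 (0.0144) and neutrophil (0.0144) genes were higher relative to other genes, and erythroid genes were lower, with a mean of -0.03 (adjusted p = 0.033). None held with an estimated correlation: the monocyte list had adjusted p = 0.217 with an estimated correlation, interferon-gamma adjusted p = 0.296, macrophage and type I interferon adjusted p = 0.393, cDC2 adjusted p = 0.397, NK and plasma cell adjusted p = 0.532, proliferation and neutrophil adjusted p = 0.623, and cDC1 and erythroid adjusted p = 0.719. The erythroid call ended after quantile normalization (adjusted p = 0.205) and without MLN Cre+ replicate 2 (adjusted p = 0.0704). The plasma cell call ended without MLN Cre+ replicate 2 (adjusted p = 0.0688), the cDC1 call without MLN Cre- replicate 1 (adjusted p = 0.173) or Cre+ replicate 3 (adjusted p = 0.345), and the neutrophil call without MLN Cre- replicate 3 (adjusted p = 0.22), Cre+ replicate 1 (adjusted p = 0.0552) or Cre+ replicate 2 (adjusted p = 0.118). Fry did not call the proliferation (adjusted p = 0.13), cDC1 (0.244), plasma cell (0.088), NK (0.088), neutrophil (0.123) and erythroid (0.879) lists in MLN. Of the TGF-beta pathway list Tgfbi alone was called, 1 of 30 by both adjustments, and 0 of 23 retinoic acid genes were called (1 adjusted over the list alone). The 16 lists not called had camera adjusted p from 0.0678 to 0.812. Cytokine and chemokine genes were called as higher after quantile normalization (adjusted p = 0.0124 and adjusted p = 0.0324) and by fry (adjusted p = 0.00589 and adjusted p = 0.00597).

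Omitting single arrays also brought lists past the threshold in MLN. Cytokine genes were called without spleen Cre+ replicates 1 (adjusted p = 0.04), 2 (adjusted p = 0.0459) or 3 (adjusted p = 0.0417), MLN Cre- replicate 2 (adjusted p = 0.0181) or MLN Cre+ replicate 3 (adjusted p = 0.0244). Chemokine genes were called without MLN Cre- replicate 2 (adjusted p = 0.0464) or MLN Cre+ replicate 3 (adjusted p = 0.0332). Antigen presentation genes were called as higher and stress genes as lower without MLN Cre- replicate 3 (adjusted p = 0.0477 and adjusted p = 0.0177). T cell genes were called as lower without spleen Cre+ replicate 1 (adjusted p = 0.0378) or MLN Cre+ replicate 3 (adjusted p = 0.0244).

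The MLN count rested on single arrays. It was 0 without MLN Cre- replicate 2, Cre+ replicate 1 or Cre+ replicate 2, 1 without Cre+ replicate 3, 2 without Cre- replicate 1 and 42 without Cre- replicate 3, and it was 11, 13 and 9 without spleen Cre- replicate 2, spleen Cre- replicate 3 and spleen Cre+ replicate 2. Fitting the 6 MLN arrays alone gave 0 calls in limma, and quantile normalization gave 53. Of the 15 named genes called in MLN, 0 stayed called in each of the 12 omissions, although 15 kept their direction; the log2 difference of Fcgr4 ranged from 1.64 to 2.09 (adjusted p from 0.0271 to 0.114), and that of Itgam from 0.90 to 0.98 (adjusted p from 0.013 to 0.114).

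**Figure D3:**
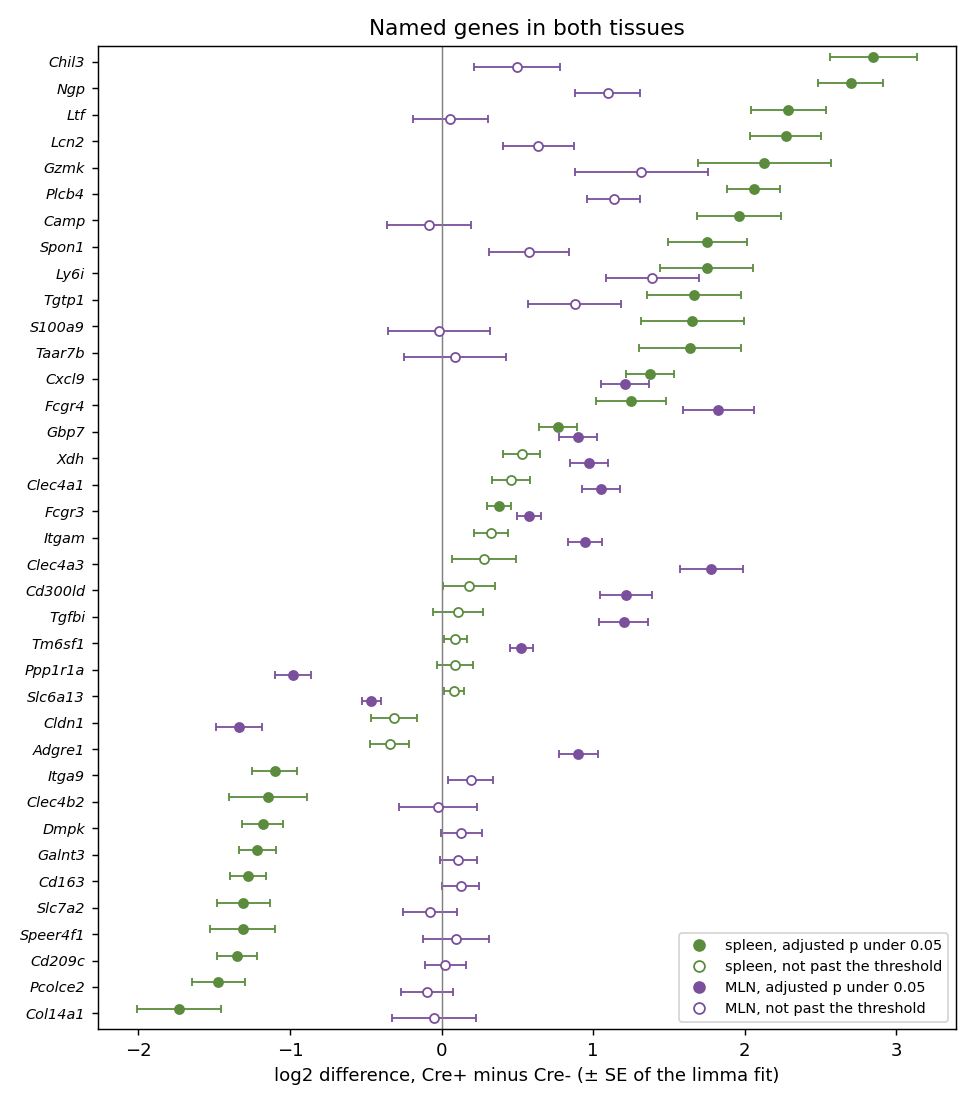
Log2 differences, Cre+ minus Cre-, with the SE of the limma fit, for the 37 genes named as largest rises or falls in spleen or MLN, without the Y-linked genes. Green points are spleen and purple points MLN, filled where the adjusted p was under 0.05; Fcgr4, Fcgr3, Gbp7 and Cxcl9 were filled in both tissues.

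Whether the genotype difference differed between tissues was tested directly, as the MLN difference minus the spleen difference. The differences of 5 macrophage genes ran apart: Mertk by 1.43 (SE 0.18, adjusted p = 0.0221), Cd163 by 1.40 (SE 0.169, adjusted p = 0.0186), Axl by 1.31 (SE 0.21, adjusted p = 0.0452), Fcna by 1.30 (SE 0.202, adjusted p = 0.044) and Adgre1 by 1.24 (SE 0.182, adjusted p = 0.0352) were all more positive in MLN. The same held for the growth factor Igf1 (1.15), Il1a (1.13), Cd209c (1.38), Galnt3 (1.33), Dmpk (1.31) and Itga9 (1.29), and for the Y-linked Eif2s3y (6.91) and Kdm5d (3.88). The granule gene Ltf (-2.23, SE 0.35, adjusted p = 0.044) and Ppp1r1a (-1.07, SE 0.166, adjusted p = 0.044) were more negative in MLN. Mean levels in MLN Cre- and Cre+ were 5.95 and 6.07 for Cd163, 6.07 and 6.09 for Cd209c, and 5.56 and 5.67 for Galnt3. They were 6.08 and 6.28 for Itga9, 5.75 and 6.18 for Il1a, and 5.99 and 6.05 for Ltf. All lay below 6.37, the cutoff set for dim probe sets. For these genes the contrast came mostly from spleen and does not show an opposite response in MLN. Of the 5 macrophage genes, Adgre1 alone was called in MLN itself. Tgfbr2 had 0.12 (SE 0.106, adjusted p = 0.681). In all 38 probe sets were called, 32 more positive and 6 more negative in MLN, and 2845 had an unadjusted p under 0.05 against 1167 by chance.

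All 23 macrophage genes were more positive in MLN than in spleen, with a median of 0.96, and 5 were called (17 adjusted over the list alone). The camera adjusted p was 5.95e-20, and adjusted p = 0.269 with an estimated correlation. Of 18 neutrophil genes 1 was called as more negative (8 more negative and 1 more positive adjusted over the list alone), with a list mean of -0.75 (adjusted p = 2.75e-09, and adjusted p = 0.269 with an estimated correlation). Plasmacytoid DC genes had 0 of 16 called (7 more positive adjusted over the list alone), with a mean of 0.38 (adjusted p = 1.64e-05, and adjusted p = 0.269 with an estimated correlation). The proliferation list had 0 of 25 called by either adjustment and a mean of -0.30 (adjusted p = 4.53e-08, and adjusted p = 0.772 with an estimated correlation). Type I interferon-induced genes (0 of 24 by either adjustment, mean -0.25, adjusted p = 0.0011, and adjusted p = 0.798 with an estimated correlation) lost the call after quantile normalization (adjusted p = 0.0911). Also called were the cDC2 list (6 of 24 adjusted over the list alone, mean 0.28, adjusted p = 0.00378, and adjusted p = 0.772 with an estimated correlation), the NK list (0 of 16 by either adjustment, mean 0.37, adjusted p = 0.016, and adjusted p = 0.901 with an estimated correlation) and the erythroid list (1 of 18 adjusted over the list alone, mean -0.15, adjusted p = 0.0307, and adjusted p = 0.901 with an estimated correlation). The spleen side of each of these differences carries the sex difference between the splenic groups.

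The interaction count was 12 without spleen Cre- replicate 1, 11 without spleen Cre- replicate 2, 7 without MLN Cre- replicate 1, 6 without MLN Cre- replicate 2, 7 without MLN Cre+ replicate 1, 5 without MLN Cre+ replicate 2 and 5 without MLN Cre+ replicate 3. The balance of 32 to 6 became 16 to 14 without spleen Cre+ replicate 2, 21 to 10 without spleen Cre+ replicate 3, 43 to 12 without spleen Cre- replicate 3 and 33 to 13 with arrays shifted to 1 median. Of the 15 named genes called here, Eif2s3y was the 1 that stayed called in each of the 12 omissions, 15 kept their direction, and 11 stayed called after quantile normalization, which ended the calls of Kdm5d, Cd209c, Itga9 and Ltf. The cDC2 call ended without spleen Cre+ replicate 3 (adjusted p = 0.0836), the erythroid call without spleen Cre- replicate 3 (adjusted p = 0.0834) or spleen Cre+ replicate 3 (mean 0.01, adjusted p = 0.542) and after quantile normalization (adjusted p = 0.0911), and the NK call without spleen Cre- replicate 3 (adjusted p = 0.179), spleen Cre+ replicate 1 (adjusted p = 0.292), MLN Cre- replicate 2 (adjusted p = 0.0541) or MLN Cre- replicate 3 (adjusted p = 0.0775). Of the 8 lists called here, fry called the macrophage (adjusted p = 0.0154) and plasmacytoid DC lists (0.0382), and not the type I interferon (0.692), proliferation (0.632), cDC2 (0.133), NK (0.692), neutrophil (0.117) and erythroid lists (0.852).

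Other lists were called for the difference between tissues only in some fits. Monocyte genes were more positive in MLN after quantile normalization (adjusted p = 0.00455) and without spleen Cre+ replicate 1 (adjusted p = 0.0394). T cell genes were more negative without spleen Cre- replicate 3 (adjusted p = 0.0104), spleen Cre+ replicate 1 (adjusted p = 2.58e-10), MLN Cre- replicate 3 (adjusted p = 0.0388) or MLN Cre+ replicate 3 (adjusted p = 0.0216). Antigen presentation genes were more negative without spleen Cre+ replicate 3 (adjusted p = 0.00738) or MLN Cre- replicate 1 (adjusted p = 0.0261), stress genes without spleen Cre+ replicate 3 (adjusted p = 0.00738) or MLN Cre- replicate 3 (adjusted p = 0.00496), and cDC1 genes without spleen Cre+ replicate 3 (adjusted p = 0.036) or MLN Cre+ replicate 3 (adjusted p = 0.0216). B cell and mast cell genes were more negative without spleen Cre- replicate 3 (adjusted p = 0.0377 for both).

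Genotype differences in spleen and MLN were then set side by side. Fcgr4 rose by 1.25 in spleen and 1.83 in MLN, Cxcl9 by 1.38 and 1.21, Gbp7 by 0.77 and 0.90, and Fcgr3 by 0.38 and 0.58. With an unnamed probe set they made 5 that rose in both tissues, where independent lists would share 0.211, and 1 further unnamed probe set fell in spleen and rose in MLN. Both comparisons used the same spread estimate for each probe set, so the lists are not independent and 0.211 may be too low. Of the 290 probe sets that rose in spleen, 260 (89.7%) had a positive difference in MLN, with a median of 0.20 against 0.08 for all probe sets. Of the 217 that fell, 89 (41%) had a negative difference in MLN. With arrays shifted to 1 median, 224 of the 290 (77.2%) and 92 of the 217 (42.4%) were positive, so the majority of the latter turned to negative. Across all probe sets the differences of both tissues correlated weakly (Pearson r 0.0691, Spearman rho 0.074), with 53.55% of equal sign. Of 100 splits of the arrays 17 gave an r as large, the others ranging from -0.173 to 0.168, so this correlation was not beyond chance. No array entered both differences, and genes are not independent replicates.

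Averaged over both tissues, the granule protein gene Ngp had the largest rise among named genes. It rose by 1.90 (SE 0.152), Gzmk by 1.73 (SE 0.31), Chil3 by 1.68 (SE 0.201), Plcb4 by 1.60 (SE 0.124), Ly6i by 1.57 (SE 0.217), Fcgr4 by 1.54 (SE 0.164), Lcn2 by 1.46 (SE 0.165), the resistin-like Retnlg by 1.42 (SE 0.269), Cxcl9 by 1.29 (SE 0.112), Tgtp1 by 1.27 (SE 0.219), Oasl2 by 1.20 (SE 0.158) and Ltf by 1.17 (SE 0.175). Beside the Y-linked genes, Cldn1 fell by 0.83 (SE 0.107), Pcolce2 by 0.78 (SE 0.122), Slc7a2 by 0.69 (SE 0.124) and Cd209c by 0.66 (SE 0.0944). The averages of Ltf (2.29 in spleen and 0.06 in MLN) and Cd209c (-1.35 and 0.03) came from spleen, and both genes were called for the difference between tissues. Set against the differences given above for each tissue, the averages of Pcolce2, Slc7a2, Chil3 and Lcn2 also came mostly from spleen, and that of Cldn1 mostly from MLN. Ngp rose less in MLN (1.10, adjusted p = 0.121) than in spleen. The splenic part of every average carries the sex difference between the splenic groups. In all 293 probe sets were called, 239 up and 54 down. Of the type I interferon list 12 of 24 rose (21 rose and 1 fell adjusted over the list alone), of the interferon-gamma list 7 of 16 (10 adjusted over the list alone), of the monocyte list 7 of 15 (11 adjusted over the list alone), of the neutrophil list 7 of 18 (15 adjusted over the list alone) and of the proliferation list 8 of 25 (23 adjusted over the list alone). Camera called 13 of the 27 lists and none held with an estimated correlation, the lowest being adjusted p = 0.0951 with an estimated correlation, shared by the type I interferon, interferon-gamma, monocyte and neutrophil lists. Tgfbr2 fell short of the threshold (-0.18, SE 0.053, adjusted p = 0.13). The count was 157, 142, 185 and 103 without spleen Cre- replicates 1 and 2 and spleen Cre+ replicates 1 and 2, and 109, 62, 692, 149, 121 and 116 without MLN Cre- replicates 1, 2 and 3 and MLN Cre+ replicates 1, 2 and 3. It was 183 after quantile normalization. Of the 52 named genes called, 27 stayed called in each of the 12 omissions.

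Most probe sets were called between the control isolates of MLN and spleen. Tissue coincided with magnetic sorting of CD11c+ cells in spleen and flow sorting of CD11c+CD103+ cells in MLN. Tissue and isolation therefore cannot be told apart. The Y-linked Eif2s3y differed too, at -2.48 in MLN Cre- against spleen Cre-. Aldh1a2, the retinal dehydrogenase that makes retinoic acid in gut DC, was higher in MLN by 3.80 (SE 0.145, adjusted p = 1.4e-08) as deposited and by 4.44 after quantile normalization. The ferroportin gene Slc40a1 was lower by 6.00 as deposited, with a value of -5.59 after quantile normalization, and the decoy receptor Il1r2 (-5.46 and -4.95), the eotaxin receptor Ccr3 (-5.09 and -4.63), Hpgd (-5.09 and -4.54), S100a8 (-4.87 and -4.67), the mannose receptor Mrc1 (-4.52 and -4.02), Fcgr4 (-4.46 and -3.95) and the haem oxygenase Hmox1 (-4.46 and -3.68) were also lower in MLN. Of 23 macrophage genes 21 were lower and 1 higher, with a median of -3.72 as deposited and -2.82 after quantile normalization, and of 15 monocyte genes 14 were lower (-2.75 and -1.94). Of 17 T cell genes 13 were higher and 0 lower, with medians of 0.88 and 1.70, including Cd3e at 1.48 and 2.48. Of 24 cDC2 genes 21 were lower (medians -2.28 and -1.24). Tgfbr2 was lower by 1.36 as deposited, and its difference after quantile normalization was -0.20 (adjusted p = 0.0714).

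The balance of these calls depended on the scaling and on dim probe sets. As deposited, 17559 probe sets were called, 6134 higher and 11425 lower in MLN (34.9% higher), and the median of all probe sets was -0.36. With arrays shifted to 1 median the share higher was 47.2% and the median -0.06, and after quantile normalization 53.6% and 0.03, of 14962 called. Without dim probe sets the share moved the other way, to 17.8% of 12857 called. Camera, which sets a list against other genes, called 11 of 27 lists, of which T cell genes were higher (adjusted p = 0.0011). Macrophage (2.05e-05), stress (2.92e-05), cDC2 (0.000313), monocyte (0.0011), plasmacytoid DC (0.00132), cDC1 (0.0119), TGF-beta pathway (0.0162), proliferation (0.0162), B cell (0.0203) and NK genes (0.0262) were lower, and of these lists the B cell median turned, from -0.81 to 0.15, after quantile normalization. Named genes turned as well, among them Edem1 from -0.61 to 0.50, Ctsw from -0.46 to 0.64 and Irf9 from -0.96 to 0.17. None held with an estimated correlation, with adjusted p from 0.595 to 0.601 with an estimated correlation. A gene group chosen after its values were seen, 801 probe sets of olfactory and vomeronasal receptor genes such as Olfr46 (4.41) and Vmn1r15 (4.17), was also higher in MLN, with a median difference of 1.45 (698 higher and 4 lower) as deposited and 1.20 after quantile normalization. These receptors of sensory neurons had median levels of 3.73 in spleen and 5.57 in MLN, and of 3.98 and 5.41 after quantile normalization. All lay below 6.37, the cutoff set for dim probe sets, so the difference does not show expression of these genes in MLN.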

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

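The tests of explanations in this part were chosen after the results they address were seen. The direct comparison of tissues singled out 15 genes and 8 lists by their tests. Each of the 8 list calls was lost with an estimated correlation, at adjusted p = 0.269 to adjusted p = 0.901, and fry called 2 of the 8. In MLN minus spleen terms the values were 6.91 for Eif2s3y, 3.88 for Kdm5d, 1.43 for Mertk, 1.40 for Cd163, 1.38 for Cd209c, 1.33 for Galnt3, 1.31 for Dmpk, 1.31 for Axl, 1.30 for Fcna, 1.29 for Itga9, 1.24 for Adgre1, 1.15 for Igf1, 1.13 for Il1a, -1.07 for Ppp1r1a and -2.23 for Ltf. The list means were 0.86 for macrophage, 0.38 for plasmacytoid DC, 0.37 for NK and cytotoxic, 0.28 for cDC2, -0.15 for erythroid, -0.25 for type I interferon-induced, -0.30 for proliferation and -0.75 for neutrophil genes.

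Other groupings of the arrays were counted for each number of calls. For spleen, 1 of the 10 splits of the 6 arrays, the real one, gave as many as 507 calls and the highest other gave 3. For MLN, 1 of 10 gave as many as 20 and the highest other gave 1, and for MLN against spleen 1 of 10 gave as many as 17559 and the highest other gave 0. With 10 splits no share under 0.05 can arise. For the difference between tissues, 2 of 100 splits gave as many as 38 calls. Regrouping within both tissues removes every genotype difference, so this share does not exclude chance for a difference between tissues. The other split, with 293, keeps both real groupings and only exchanges the names of the MLN groups, which turns it into the averaged contrast; the next gave 30, and those with regrouped splenic arrays at most 2, so the count followed the splenic groups, which coincide with sex. That count is thus the averaged genotype difference itself. It is no evidence that the tissues agree, since 17 of 100 splits gave a correlation between them as large as the real 0.0691. For the averaged contrast, 2 of 100 gave as many as 293, and the other one, with 362, kept the real splenic groups and exchanged 1 array between the MLN groups. No split with regrouped splenic arrays gave more than 1 call there, so this count too followed the splenic groups. Their grouping has 10 splits, which cannot give a share under 0.05 alone. The share of 2 in 100 thus rests on regrouped MLN arrays, where 1 split gave more calls, and it does not exclude chance. Sex on the splenic side stays open as well.

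The first pattern is the set of splenic calls, where sex and genotype coincide. If sex were the whole cause, genes that rose in spleen would not shift in MLN, provided both MLN groups held the same sex mix. Y-linked genes did not separate those groups, but Eif2s3y ranged from 6.27 to 8.2 over the MLN arrays. Its Cre+ level in MLN was 113% of Cre- with an interval of 59.5 to 216, so unequal mixes were not excluded. With arrays at 1 median, the 290 rising probe sets had a median MLN difference of 0.128 (224 positive), and fry's rotation test passed 0.05. Because the sex mix of the MLN groups is uncertain, this shift does not decide whether sex was the whole cause of the rises. Sex may account for part or all of each rise. The 217 falling probe sets had a median of -0.0395 (92 positive), and fry did not pass. For them too sex and genotype cannot be told apart, because the design gives no splenic arrays of the other pairing.

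The second pattern is the rise of neutrophil genes in spleen. More neutrophil-lineage cells in the magnetic isolate is a candidate explanation that was not tested apart from the pattern itself: the list median was 1.02, and the abundant transcripts S100a8 and S100a9 rose by 1.54 and 1.66, while Csf3r (-0.04) and Mmp9 (0.12) did not follow (S100a8 and Mmp9 were chosen after their values were seen). Of the 18 genes, 2 stand on another list as well. Sex as the whole cause cannot be told apart, since in MLN the list had a median of 0.151 with arrays at 1 median (12 of 18 positive), and fry did not pass. An effect of the deletion stays open too.

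The third pattern is the macrophage list, of which 6 of 23 genes fell in spleen and 1 of 23 rose in MLN. Separate normalization of the tissues was examined by joint quantile normalization. After it the difference between tissues had a median of 0.972 (23 of 23 positive), and fry passed 0.05. The difference thus remained when all arrays had 1 value distribution. That does not decide on separate normalization as the cause, because an offset between tissues cancels in this difference whatever the scaling. Separate runs on the probe level are also not undone by joint quantile normalization. In MLN the macrophage list stood above the T cell, B cell, erythroid and platelet lists by 0.464 (2 SE either side, 0.241 to 0.687), but the NK (median 0.59), plasma cell (0.37) and neutrophil (0.22) lists were not part of that test, so a larger share of other cell types stays open. More macrophage-like and monocyte-like cells may account for the MLN side. That 38 of the 38 genes of both lists were positive there (21 of 23 and 14 of 15 after quantile normalization) restates the pattern and does not test this. How many such cells passed the gate on CD11c and CD103 was not measured. In MLN Cre- the B cell gene Cd79b measured 12.5 and the T cell gene Cd3e 11.3. The upper quartiles of these arrays lay between 7.95 and 8.14, so the sort may have held other cell types. The same holds for the splenic isolate. In spleen Cre- Cd79b measured higher than in MLN Cre- and Cd3e lower, and each lay above the upper quartiles of the spleen Cre- arrays. Splenic differences may therefore also include those of cells other than DC. A change of expression within the DC, and sex on the splenic side, stay open.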

How the results depend on the processing

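The tests in this part were fixed beforehand except where said. Direction held for the named genes called between genotypes and the lists called in spleen, MLN or interaction, except that the mean of the erythroid list between tissues turned from -0.15 to 0.01 without spleen Cre+ replicate 3. Between MLN and spleen, quantile normalization turned the median of the called B cell list from -0.81 to 0.15, those of 6 lists not called (antigen presentation, both interferon lists, Notch, core conventional DC and plasma cell) from negative to positive, and some named genes. The side of the threshold often did not hold, and the cause was not tested except where fewer arrays or another threshold make it plain. Main counts were 507 (spleen), 20 (MLN), 38 (interaction), 293 (average) and 17559 (MLN against spleen). Quantile normalization gave 286 for spleen, 53 for MLN and 183 for the average, and lowered the correlation of both tissues' differences to 0.031. Without dim probe sets MLN had 39, interaction 74 and average 553, and with 1-symbol probe sets 32, 68 and 498. Array weights gave 2747, 966, 1007 and 3044 for spleen, MLN, interaction and average, and brought Tgfbr2 in spleen (-0.23) past the threshold at adjusted p = 0.0477, against 0.0953 to 0.292 in its other alternatives. An adjusted p under 0.1 gave 1054, 52, 130 and 779. At least 1.5-fold left 112 for the average. An unadjusted p under 0.05 with at least 2-fold gave 230, 88, 416, 47 and 8317. The arrays of 1 tissue alone gave 18 for spleen and 0 for MLN, with 4 fewer residual degrees of freedom. With an estimated correlation 0 list calls stood in spleen and MLN, against 20, and fry ended 1 call in spleen, 6 in MLN and 6 in interaction.

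Leaving out single arrays gave 141 to 519 for spleen, 0 to 42 for MLN, 5 to 55 for interaction, 62 to 692 for the average, 16478 to 17665 for MLN against spleen, 18 to 25 list calls and a correlation of 0.000169 to 0.126. Replicate numbers were not taken to pair the samples, because r between the deviations of same-numbered arrays did not pass 0.1 in every pair: it was -0.142 to -0.00259 in spleen and 0.00149 to 0.31 in MLN. In MLN 2 of 3 correlated best with their own number, a hint from the data and not from the design. A replicate block within tissue gave 281, 0, 0 and 162 calls for spleen, MLN, interaction and average, without the neutrophil list call in MLN (adjusted p = 0.113) and with a T cell list call for interaction (adjusted p = 0.03), and a replicate block across groups gave 2 for MLN and 10 for interaction. Leaving out probe sets assigned to X and Y, chosen after seeing the data, gave 486, 20, 35, 270 and 17142. RMA values give no signal over background, so probe sets near the floor could not be set apart by detection.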

Other observations

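These counts were picked out after the results were seen, and no explanation was tested. Among 18 core conventional DC genes 0 were called in spleen or MLN over all genes or adjusted over the list alone, with medians of 0.08 and 0.10, and among 27 costimulation and maturation genes 0 were called in either tissue (1 in MLN adjusted over the list alone), with medians of 0.13 in both. After quantile normalization the MLN medians were -0.05 for the core genes (6 positive, against 16 as deposited) and 0.006 for the costimulation genes. Of 23 retinoic acid and gut-DC genes 0 were called in either tissue, with medians of 0.00 and -0.01, and Tgm2 had 0.70 (adjusted p = 0.196) in MLN. Among 19 Notch genes 0 were called by either adjustment in either tissue.

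In control DC, maturation genes ran in both directions between tissues. Of 27 such genes 10 were higher and 8 lower in MLN as deposited, with a list median of 0.169. After quantile normalization 19 were higher and 5 lower, with a list median of 0.795. Among the lower genes were Cd86, at -3.00 as deposited and -1.95 after quantile normalization, and Cd80, at -2.55 and -1.46.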
